A study of Danio rerio with 8 samples.

How the data were processed

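RNA sequencing libraries of sorted zebrafish endothelial cells at 3 days post fertilisation, 4 from ddx21 mutants and 4 from siblings, were analysed from 2 deposited tables. The first holds read counts per Ensembl gene for 32520 genes, which the authors deposited as raw values: they are whole numbers, with library totals from 38459219 to 51173007. Per the submitters' processing notes the tools were FastQC, Subread 2.0.0, featureCounts and edgeR, with the genome build GRCz11. Their order, the strand setting, the annotation release and any filter are not given in the sources used here. The second deposited table is labelled as normalised, batch-corrected log2 CPM. Every 1 of its 260160 values equalled the log2 of CPM + 1 computed from the deposited counts and their library totals (largest difference 5e-14, tolerance 1e-09), so the deposited log2 values hold neither a batch correction nor a composition factor. Their values were used only as an alternative and for a comparison with the fitted fold changes. Reads of overlapping genes, antisense partners and near-identical paralogues may be split or lost in such counts, which matters most for the duplicated genes of ribosomal proteins, crystallins, keratins and pancreatic proteases.

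Groups and replicate numbers came from the sample titles, and every table column was matched to its sample by the short name in the labels. All values below were computed for this text. Counts were filtered with edgeR 4.0.16 (filterByExpr by group, minimum count 10, minimum total 15), which kept 18549 genes, scaled by TMM and fitted with the quasi-likelihood model (robust) with the group as the only term, in R 4.3.3. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, or over the members of 1 list where the text says "adjusted over the list alone". CPM are TMM-normalised, with mean ± SD over 4 libraries, and log2 fold changes are mutant over sibling. For 10 genes fixed beforehand (among them DDX21, cdkn1a, mdm2, PROX1, lyve1b, FLT4, VEGFC, kdrl, FLI1) a two-sided exact permutation test of log2(CPM + 0.5) was added, whose smallest p with 4 against 4 is 0.029. It did not use the pairing of the libraries. Even mdm2, at that smallest exact p, had an adjusted p of 0.14 over the 10 genes. Not passing this test after adjustment therefore says little about a gene. At 38459219 reads or more per library the error of counting reads is small, and the spread between libraries limits the precision: the median trended dispersion was 0.61. The number of reads does not show how many RNA molecules were sampled before sequencing, which was not tested.

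Before the data were examined the groups, the main design, the alternatives, the rule for named genes and 28 gene lists were fixed: ribosome biogenesis factors, RNA polymerase I machinery, cytosolic ribosomal proteins, p53 target genes, apoptosis machinery, DNA replication and S phase, mitosis, lymphatic, venous, arterial and pan-endothelial markers, Vegfc pathway components, ERK feedback and immediate early genes, integrated stress and unfolded protein response, heat shock proteins, interferon-stimulated genes, glycolysis, cholesterol biosynthesis, mitochondrially encoded transcripts, and markers of erythroid cells, leukocytes, nerve, muscle, epidermis, neural crest, cartilage, fibroblasts and liver with yolk. The last 9 are the other cell types that the gate could let through. Of 1033 list symbols 930 (90.0%) matched an identifier, 125 of them through a human-style symbol such as FLT4 for flt4. A name table gave symbols to 29201 of the 32520 identifiers, and synonyms came from a RefSeq gene table of the assembly GRCz12tu, of which no coordinate was used. Where several identifiers shared a human-style symbol the identifier stands beside it, since which duplicate it is was not settled. Some genes are on more than 1 list: 10 of the 23 lymphatic markers and 6 of the 35 p53 targets are also on another. Lists were tested with camera on the edgeR fit (limma 3.58.1, preset correlation 0.01, two-sided), adjusted over the 28 lists, and again with the correlation estimated from the residuals and with fry. Lists of exocrine pancreas, intestinal and lens genes were drawn up after the values had been seen and form a family of 3.

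Named genes were, by the fixed rule, DDX21; the genes past the threshold with the largest change and no overlap between groups, or else the 5 with the smallest p in each direction with a mean of at least 5 CPM; the same from the fit with the block; up to 4 members of each list with the smallest p; and the fixed genes. Further list members that passed in either fit, krt4 and cdh5 for their levels, and genes of the 3 later lists were named after their values had been seen. Replicates of a group were compared before averaging: their counts differed far beyond sampling noise (chi-square per degree of freedom 121 to 897), so each counted as 1 replicate. Whether the replicate numbers pair the libraries was checked on the counts: deviations from the group means correlated between same-numbered libraries at 0.14, 0.23, 0.11 and 0.27 over 18549 genes, and every mutant correlated best with the sibling of its own number. The labels do not say what a number stands for, so the pairing comes from the data. The fit with the number as a block was therefore computed for every result. In a principal component analysis (PC1 30%, PC2 20.5% of the variance) mutant 4 and sibling 4 lay at the end of PC1 and mutant 1 alone at the end of PC2.

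Alternatives were the replicate block, 3 other scalings, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, 1 surrogate variable (sva 3.50.0), limma on the deposited log2 CPM, other thresholds, and leaving out each library or pair. Added after seeing the data were the block in DESeq2 and in limma-voom, leaving out the 3 libraries of lowest quality weight, the mean log2 CPM of the epidermal markers as a covariate, and the block with an estimated correlation.

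The scripts were tested on simulated counts for the mutant against sibling comparison, with 50 genes changed at each of 4 fold sizes among 17149 tested. edgeR recovered 2% of the genes changed 2-fold, 56% at 4-fold, 76% at 8-fold and 82% at 16-fold and called 13 unchanged genes; with the block it recovered 0%, 46%, 74% and 80% and called 5. DESeq2 recovered 2%, 72%, 94% and 96% but called 114 unchanged genes, and limma-voom 0%, 50%, 64% and 74% with 8. A list of 30 genes shifted 1.5-fold was missed by camera (adjusted p = 0.19; adjusted p = 0.5 with an estimated correlation), and one shifted 2-fold, added after that miss, was called (adjusted p = 1.4e-08; adjusted p = 0.023 with an estimated correlation); 0 of 28 unchanged lists were called. Nothing was left out of the counts, results for some single genes that the rule names are not reported here, and genome coordinates were not used here.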

Results

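Gene expression was measured by RNA sequencing in cells sorted as endothelial from zebrafish embryos at 3 days post fertilisation. The cells carried 2 fluorescent reporters, a nuclear green one under fli1a control, which marks endothelium, and a red one under lyve1b control, which marks veins and lymphatics. Cells positive for both were sorted to collect venous and lymphatic endothelial cells. There were 4 libraries from embryos mutant for ddx21 and 4 from embryos labelled as siblings, whose own genotype the labels do not give, and both groups carried replicate numbers 1 to 4. Ddx21 is a nucleolar RNA helicase with a role in making ribosomes. The series title ties it to lymphatic development driven by the growth factor Vegfc, to ribosome biogenesis and to signalling through p53 and its target p21. The deposited counts held from 38459219 reads in sibling 1 to 51173007 in mutant 4 over 32520 genes. Between 18051 and 25329 genes per library had at least 1 read. This number did not rise with depth, as sibling 1, with the fewest reads, had the most genes. The fewest were in mutant 4, sibling 4 and mutant 1 (18051, 18064 and 19366), and the cause was not tested. Nothing in the labels says whether same-group libraries came from separate clutches or sorts, so the p-values measure the spread between these libraries, part of which may be technical.

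Of the 28 gene lists tested without the replicate block, 2 were called with an estimated correlation between genes too: targets of the tumour suppressor p53 were higher and transcripts of liver and yolk proteins were lower. With the block neither call held with an estimated correlation (adjusted p = 0.12 for each). CCNG1, a p53 target that encodes cyclin G1, measured 190 ± 79.7 CPM in siblings and 676 ± 139 CPM in mutants (SD, n = 4 each), a log2 fold change of 1.83 (SE 0.31). The liver enzyme gene ces2a, a carboxylesterase, measured 186 ± 95.7 CPM in siblings and 7.19 ± 5.29 CPM in mutants, a log2 fold change of -4.69 (SE 0.71). Of the 27 measured liver and yolk genes, 15 fell, and of the 34 measured p53 target genes 6 rose, both adjusted over the list alone. No single gene passed over all genes: edgeR called 0 of 18549 tested genes at an adjusted p under 0.05, the smallest being 0.18.

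At an unadjusted p under 0.05 edgeR gave 556 genes, 247 higher and 309 lower in mutants. Chance would give 927 on average if no gene differed, and the count can lie far from that where genes vary together. With the replicate number as a block it again gave 0 genes, with 1086 at an unadjusted p under 0.05 (552 higher, 534 lower). Other tools gave other counts: DESeq2 called 62 genes (13 higher, 49 lower) and 526 with the block, and limma-voom with quality weights called 0 and, with the block, 31. In simulated libraries of the same size and spread DESeq2 also called 114 genes that had been left unchanged, against 13 for edgeR.

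DDX21 (ENSDARG00000063626), the mutated gene, measured 312 ± 51.4 CPM in siblings and 221 ± 40 CPM in mutants (SD, n = 4 each), a log2 fold change of -0.50 (SE 0.21), and was lower in the mutant of 4 of 4 pairs. The difference did not pass (two-sided exact permutation p = 0.057, adjusted p = 0.19 over 10 genes fixed beforehand). In this exact test 4 against 4 libraries allow no p below 0.029, and mdm2, at that p, had an adjusted p of 0.14. Not passing it after adjustment therefore says little. Siblings 1 to 4 held 245, 364, 337 and 301 CPM and mutants 1 to 4 held 233, 266, 170 and 217 CPM, so that the transcript was present in every library and mutant 2 lay above sibling 1. An allele that changes the protein need not lower the transcript, and the level therefore checks the labels only weakly.

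Among the p53 targets that rose, adjusted over the list alone, were CCNG1 (edgeR adjusted p = 0.0028 over the list alone) and rps27l, a p53-induced homologue of a ribosomal protein, at 128 ± 35.6 against 328 ± 74.9 CPM (log2 1.36, SE 0.26, edgeR adjusted p = 0.0042). PHLDA3, an inhibitor of Akt, stood at 35.2 ± 21.2 against 157 ± 69.5 CPM (log2 2.16, SE 0.44). Alongside them stood mdm2, the ubiquitin ligase that degrades p53, at 48.1 ± 12.6 against 99.4 ± 5.89 CPM (log2 1.05, SE 0.23), and a GADD45A gene of the stress response (ENSDARG00000043581; log2 1.60, SE 0.49). These 5 were higher in mutants in 4 of 4 pairs. For CCNG1, rps27l, PHLDA3 and mdm2 every mutant library lay above every sibling library. Of the genes fixed beforehand, mdm2 gave the smallest exact permutation p that 4 against 4 libraries allow (0.029, adjusted p = 0.14). For cdkn1a, which encodes the cell cycle inhibitor p21, the levels were 127 ± 52.1 and 195 ± 42.2 CPM (SD, n = 4 each), a log2 fold change of 0.62 (SE 0.30) that did not pass (exact permutation p = 0.11, adjusted p = 0.20), although it was higher in 4 of 4 pairs. With the replicate block it rose within the list (log2 0.68, SE 0.16, edgeR adjusted p = 0.02 over the list alone), as did PLK3, a polo-like kinase (log2 0.84, SE 0.20, adjusted p = 0.018), which brought the count to 8. As a list the p53 targets rose, with 25 of 34 log2 fold changes above 0 and a median of 0.30 (camera adjusted p = 4.7e-07; adjusted p = 0.039 with an estimated correlation). The block kept the preset call (adjusted p = 6.2e-10) but not the other (adjusted p = 0.12 with an estimated correlation). The GADD45A call ended without mutant 1, mutant 2, sibling 2, sibling 3 or sibling 4 (edgeR adjusted p up to 0.16 over the list alone), while CCNG1, rps27l, PHLDA3 and mdm2 passed without each library in turn. Without single libraries the list's median ran from 0.24 without mutant 1 to 0.45 without sibling 2. In the same libraries the epidermal markers had a median log2 fold change of 0.29 (camera adjusted p = 0.082), and 0.42 with the block (adjusted p = 4.9e-07; adjusted p = 0.12 with an estimated correlation).

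**Figure D1:**
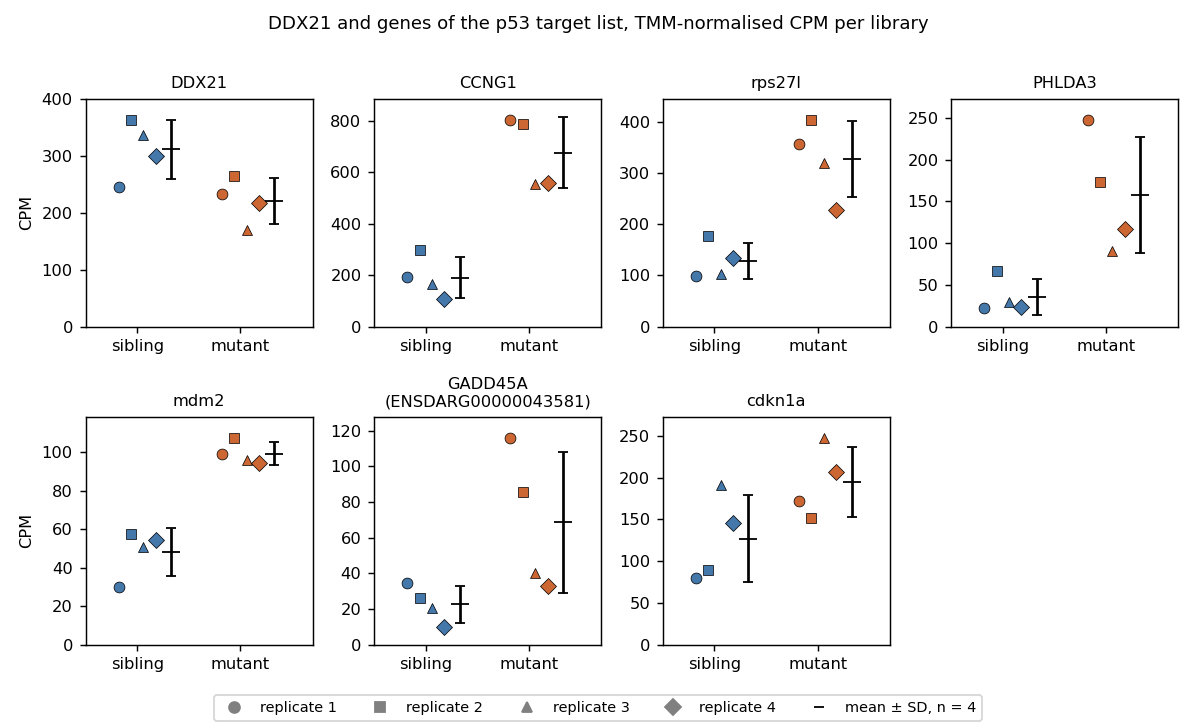
TMM-normalised CPM of DDX21 and 6 genes of the p53 target list in each library, with siblings in blue, mutants in orange, the marker shape giving the replicate number, and the bar beside the points giving mean ± SD (n = 4). CCNG1 ranges from 107 to 297 CPM in siblings and from 556 to 804 CPM in mutants, whereas the DDX21 and cdkn1a values of the groups overlap.

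Ribosome biogenesis factors, the nucleolar proteins that build ribosomal subunits, were called as higher in mutants as a list, with 73 of 104 log2 fold changes above 0 and a median of 0.13 (camera adjusted p = 0.0019; adjusted p = 0.66 with an estimated correlation). None of the 104 passed in edgeR, either over all genes or adjusted over the list alone, and 6 were higher at an unadjusted p under 0.05. The lowest p belonged to WDR3, a small subunit processome protein, at 119 ± 25 against 187 ± 17.2 CPM in mutants (SD, n = 4 each; log2 0.64, SE 0.20). Next came NAT10, an RNA acetyltransferase (log2 0.80, SE 0.31), utp3 (log2 0.74, SE 0.30) and NLE1 (log2 0.65, SE 0.26). The biogenesis call ended without mutant 1 (camera adjusted p = 0.21) or sibling 3 (adjusted p = 0.083), and the median was 0.06 and 0.08 there, against 0.25 without sibling 2 and 0.29 without mutant 4. For the RNA polymerase I machinery, which transcribes ribosomal RNA genes, the median was 0.15 (14 measured, camera adjusted p = 0.24), with polr1e at 0.49 (SE 0.31) and RRN3 at 0.47 (SE 0.32).

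Transcripts of cytosolic ribosomal proteins were called as lower as a list: 74 of 76 log2 fold changes lay below 0, with a median of -0.27 (camera adjusted p = 7.6e-08; adjusted p = 0.65 with an estimated correlation). RPL3 measured 5780 ± 267 against 3940 ± 530 CPM in mutants (SD, n = 4 each; log2 -0.56, SE 0.17) and RPL22L1, a paralogue of RPL22, 33 ± 5.19 against 12.3 ± 3.9 CPM (log2 -1.42, SE 0.32). RPS9 (log2 -0.58, SE 0.20) and RPL10A (log2 -0.59, SE 0.23) likewise held every mutant library below every sibling library. None of the 76 passed in edgeR without the block, where 4 were lower at an unadjusted p under 0.05. With it RPL22L1 and RPL3 fell (edgeR adjusted p = 0.043 for each over the list alone). The mean log2 CPM of the list was 8.04 in mutant 1 and 7.84 in mutant 4, but 8.89 and 8.50 in mutants 2 and 3. In siblings it was 8.44 to 8.86. Mutants 1 and 4 and sibling 4 had the lowest quality weights in limma-voom (0.62, 0.49 and 0.45). Without these 3 the list's median was 0.02, with 32 values below 0 (camera adjusted p = 0.87). Without single libraries the list stayed called, with a median of -0.15 without mutant 1, -0.11 without mutant 4, -0.18 without sibling 2 and -0.49 without mutant 2.

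Markers of lymphatic endothelium were called as lower as a list, with 18 of 23 log2 fold changes below 0 and a median of -0.32 (camera adjusted p = 0.036; adjusted p = 0.29 with an estimated correlation). No member passed in edgeR without the block, where 2 were lower at an unadjusted p under 0.05. These were OSR2, at 119 ± 46.2 against 53.6 ± 31.1 CPM in mutants (log2 -1.15, SE 0.40), and TBX1, a T-box factor, at 117 ± 20.7 against 82.6 ± 13.2 CPM (log2 -0.51, SE 0.21; SD, n = 4 each). With the replicate block lyve1a, a hyaluronan receptor gene, rose (log2 0.81, SE 0.13, edgeR adjusted p = 0.012 over the list alone), against the direction of the list. PROX1, the master regulator of lymphatic identity, was low throughout, at 19.3 ± 9.26 CPM in siblings and 9.61 ± 8.56 in mutants (SD, n = 4 each, exact permutation p = 0.20, adjusted p = 0.25). The reporter's own gene lyve1b did not pass (722 ± 77 and 553 ± 125 CPM, exact permutation p = 0.086, adjusted p = 0.20). Nor did the Vegfc receptor gene FLT4 (308 ± 55.6 and 246 ± 69 CPM, exact permutation p = 0.14, adjusted p = 0.20). Both were lower in the mutant of 4 of 4 pairs, and DESeq2 with the block called lyve1b (log2 -0.41, adjusted p = 0.025). The list's call ended without any 1 of mutants 1, 2 and 3 and siblings 3 and 4 (camera adjusted p up to 0.26). Its median ran from -0.53 without mutant 4 to -0.25 without mutant 1 or mutant 2.

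Venous markers had a median log2 fold change of -0.21 (13 measured, camera adjusted p = 0.08) and were called as lower with the block (median -0.25, adjusted p = 0.015; adjusted p = 0.47 with an estimated correlation). Their member stab2, a scavenger receptor gene that is also on the lymphatic list, had a log2 fold change of -0.37 (SE 0.20). Arterial markers (median -0.08, 21 measured, camera adjusted p = 0.75) and pan-endothelial markers (median -0.11, 37 measured, adjusted p = 0.50) did not pass. Of single endothelial genes, kdrl, a VEGF receptor gene, measured 370 ± 164 and 343 ± 83.3 CPM (SD, n = 4 each, exact permutation p = 0.97). FLI1 measured 1040 ± 345 and 897 ± 390 CPM (exact permutation p = 0.51) and was lower in the mutant of 4 of 4 pairs, without passing with the block either. Components of the Vegfc pathway did not pass as a list (median -0.15, 29 measured, camera adjusted p = 0.45). VEGFC itself measured 59.6 ± 24.7 against 34.1 ± 9.28 CPM in mutants (log2 -0.80, SE 0.33, exact permutation p = 0.14, adjusted p = 0.20). ERK feedback and immediate early genes, a readout of growth factor signalling, did not pass (median -0.15, 41 measured, camera adjusted p = 0.28), with the phosphatase gene DUSP1 at -0.54 (SE 0.30) and ETV4 at 0.40 (SE 0.25). In the same libraries the markers of other cell types moved too, with medians of 0.29 for the epidermal list, 0.27 for the muscle list and -2.80 for the liver and yolk list.

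Of the cell cycle, DNA replication and S phase genes were called as higher as a list (35 of 52 above 0, median 0.16, camera adjusted p = 0.041; adjusted p = 0.73 with an estimated correlation), with no member passing. MCM5, of the replicative helicase, had a log2 fold change of 0.35 (SE 0.20). The call ended without mutant 1, mutant 2, sibling 3 or sibling 4 (adjusted p up to 0.45). Mitosis genes (median 0.06, 55 measured, camera adjusted p = 0.35) and the apoptosis machinery (median -0.08, 31 measured, adjusted p = 0.87) did not pass. Glycolysis genes were called as higher (18 of 26 above 0, median 0.14, camera adjusted p = 0.04; adjusted p = 0.54 with an estimated correlation) although GAPDH, a core enzyme, measured 580 ± 214 against 301 ± 101 CPM in mutants (SD, n = 4 each; log2 -0.94, SE 0.32). No member passed, and the call ended without mutant 1, sibling 1, mutant 2, sibling 3 or mutant 4 (adjusted p up to 0.15). The integrated stress and unfolded protein response (median 0.13, 32 measured, camera adjusted p = 0.23) and heat shock proteins (median 0.14, 18 measured, adjusted p = 0.23) did not pass. Neither did interferon-stimulated genes (median 0.23, 21 measured, adjusted p = 0.75), mitochondrially encoded transcripts (median 0.09, 13 measured, adjusted p = 0.38) or cholesterol biosynthesis (median -0.32, 22 measured, adjusted p = 0.29). HSPA5, the chaperone of the endoplasmic reticulum, had every mutant library above every sibling library, at 504 ± 40.9 against 723 ± 78.6 CPM (log2 0.52, SE 0.17), without passing within its list.

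Transcripts of liver and yolk proteins fell as a list, with 24 of 27 log2 fold changes below 0 and a median of -2.80 (camera adjusted p = 1.1e-39; adjusted p = 0.0052 with an estimated correlation). Among the 15 members that fell, adjusted over the list alone, were the apolipoprotein gene apoa1b at 187 ± 107 against 25.1 ± 8.75 CPM in mutants (log2 -2.90, SE 0.45) and the transferrin gene tfa at 538 ± 398 against 33.6 ± 21.9 CPM (log2 -4.0, SE 0.78). Further such members were the protease inhibitor gene serpina1l at 32.2 ± 15.9 against 4.61 ± 1.27 CPM (log2 -2.80, SE 0.45) and the liver fatty acid binding protein gene fabp10a at 52.2 ± 25.6 against 6.25 ± 3.7 CPM (log2 -3.06, SE 0.64; SD, n = 4 each). Of the 27 members 21 were lower in the mutant of 4 of 4 pairs, where chance gives 6.25% for a single gene. In 16 every mutant library lay below every sibling library, where chance gives 1.43% for a single gene. Members can vary together across libraries, so these counts are no test of the list. Not every member went the same way. The gene apoeb, an apolipoprotein E gene, had the highest level of the list at 8690 ± 8580 and 16500 ± 16300 CPM (log2 0.92, SE 1.06) and rose with the block (log2 0.80, SE 0.22, edgeR adjusted p = 0.021 over the list alone). The fibrinogen gene FGG measured 63.7 ± 20.1 against 3.03 ± 5.98 CPM in mutants (log2 -4.39, SE 1.81) and did not pass without the block (edgeR adjusted p = 0.064 over the list alone). The block brought FGG in (log2 -8.43, SE 1.88, edgeR adjusted p = 0.012) and ended the call of apoa1a (adjusted p = 0.068), so that 15 members fell there too. With it the list gave an adjusted p of 0.12 with an estimated correlation. Without each library in turn 10 to 15 members fell. Without sibling 3 the calls of ambp, apoa1a (log2 -2.34 with it and -0.89 without), apobb.1, apoc2 and fga ended. Without single other libraries those of ambp, apoa1a, apobb.1 and serpina1 ended (edgeR adjusted p up to 0.12).

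**Figure D2:**
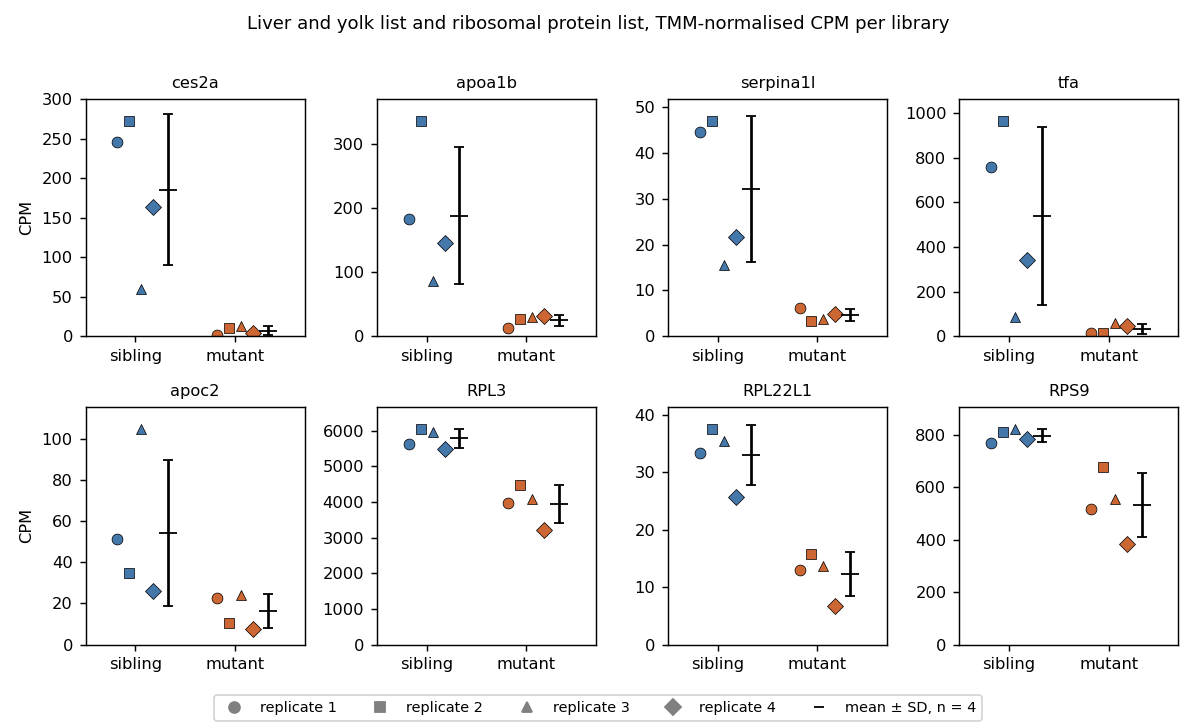
TMM-normalised CPM in each library of 5 genes of the liver and yolk list (ces2a, apoa1b, serpina1l, tfa, apoc2) and 3 of the ribosomal protein list (RPL3, RPL22L1, RPS9), drawn as siblings in blue and mutants in orange with the mean ± SD (n = 4). In each panel the 4 mutant libraries lie below the 4 sibling libraries, and RPL3 measures 5780 ± 267 CPM in siblings and 3940 ± 530 CPM in mutants.

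Markers of further cell types that the gate could let through were measurable and differed between libraries. Skeletal muscle markers were called as higher in mutants (19 of 26 above 0, median 0.27, camera adjusted p = 0.0044; adjusted p = 0.65 with an estimated correlation). No member passed without the block. With it 7 rose, adjusted over the list alone, among them the actin gene ACTA1 (ENSDARG00000055618; log2 1.32, SE 0.21) and the tropomyosin gene tpma (log2 0.82, SE 0.16). This call ended without sibling 1, mutant 2 or sibling 3 (camera adjusted p up to 0.40). Cartilage and skeletal progenitor markers were called as higher too (median 0.70, 23 measured, camera adjusted p = 0.041; adjusted p = 0.65 with an estimated correlation). So were fibroblast and mural cell markers (median 0.53, 29 measured, camera adjusted p = 0.036; adjusted p = 0.55 with an estimated correlation). Both were called only with mutants 1 and 2 and siblings 3 and 4 all included (adjusted p up to 0.40 and 0.15 without 1 of them). With the block 5 fibroblast members rose, adjusted over the list alone, against 0 without it, among them the collagen gene COL1A1 (log2 0.91, SE 0.15) and the matrix protease gene MMP2 (log2 0.91, SE 0.19).

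Epidermal and epithelial markers did not pass without the block (median 0.29, 31 measured, camera adjusted p = 0.082) and were called as higher with it (median 0.42, adjusted p = 4.9e-07; adjusted p = 0.12 with an estimated correlation). With the block 8 members rose against 0 without it, adjusted over the list alone, among them epcam, an epithelial adhesion gene (log2 0.87, SE 0.12), and the keratin gene krt4 (log2 0.87, SE 0.19). Single libraries moved the median without the block, to 0.98 without sibling 2, 0.67 without mutant 4, 0.58 without mutant 3 and 0.56 without sibling 1, where the list was called as higher (camera adjusted p = 0.00047 to 0.011). The median was 0.08 without sibling 3, 0.05 without mutant 1, -0.01 without mutant 2 and -0.02 without sibling 4, where it was not (adjusted p up to 0.93). Their levels differed more between replicate numbers than between genotypes. For krt4 they were 54800 and 19100 CPM in mutant 1 and sibling 1, and 35100 and 26700 in mutant 2 and sibling 2. They were 7690 and 5070 in mutant 3 and sibling 3, and 3090 and 1590 in mutant 4 and sibling 4. The endothelial cadherin gene cdh5 ran from 161 CPM in mutant 1 to 602 CPM in mutant 4. In both libraries of replicates 1 and 2 the mean log2 CPM of the epidermal list lay above that of the pan-endothelial list (7.83 and 6.5 in mutant 1). In those of replicates 3 and 4 it lay below (4.48 and 7.85 in sibling 4). The lists hold different genes, so these means do not measure shares of cells. Erythroid markers were called as lower (median -0.55, 19 measured, camera adjusted p = 0.028; adjusted p = 0.61 with an estimated correlation). This call ended without mutant 1, mutant 2, sibling 3 or sibling 4 (adjusted p up to 0.31). With the block the transcription factor gene klf17 fell (log2 -0.79, SE 0.15, edgeR adjusted p = 0.024 over the list alone). Macrophage and other leukocyte markers did not pass (24 measured, median 0.06, mean -0.01, camera adjusted p = 0.42, its test pointing lower). Of them the antigen presentation gene cd74a fell, at 18.1 ± 7.08 against 4.15 ± 1.28 CPM in mutants (log2 -2.12, SE 0.46, edgeR adjusted p = 0.024 over the list alone). It did not pass with the block (adjusted p = 0.051), nor without mutants 1, 2 or 3 or siblings 2, 3 or 4 (adjusted p up to 0.11). Neural markers (median -0.59, 25 measured, camera adjusted p = 0.11) and neural crest and pigment markers (median -0.58, 17 measured, adjusted p = 0.089) did not pass.

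**Figure D3:**
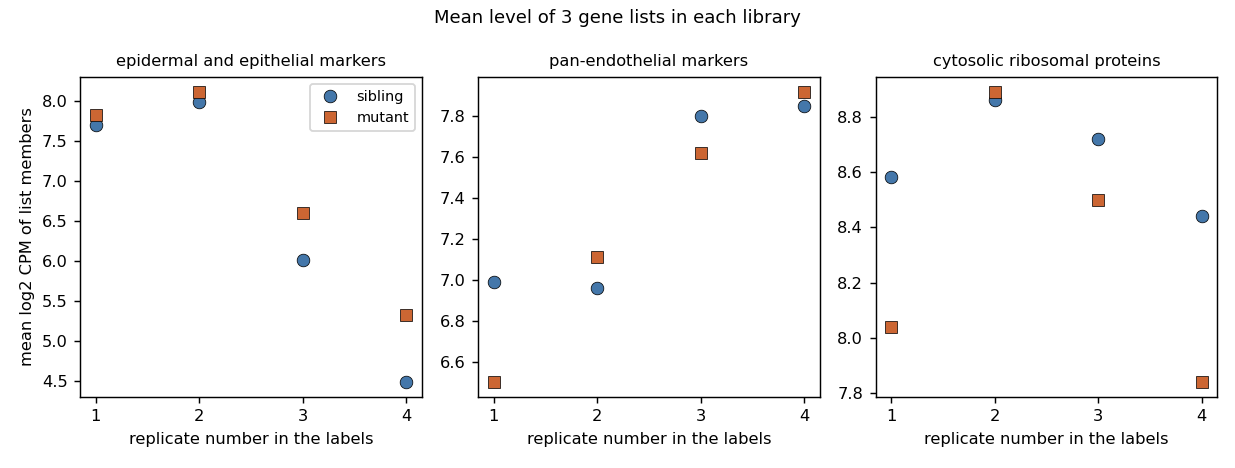
Mean log2 CPM of the members of 3 gene lists in each library against the replicate number in the labels, with siblings as blue circles and mutants as orange squares; replicate numbers have no order. The epidermal mean runs from 4.48 in sibling 4 to 8.12 in mutant 2, and the ribosomal protein mean is lowest in mutants 1 and 4 (8.04 and 7.84).

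In all, camera called 11 of the 28 lists with its preset correlation (7 higher, 4 lower). It called 13 with the replicate block (8 higher, 5 lower). With an estimated correlation 2 calls held, p53 targets and liver and yolk markers, and with the block 0. Counts of lists changed when single libraries were left out. Of the 26 lists other than p53 targets and ribosome biogenesis factors 9 were called, but 4 without mutant 1, 2 without mutant 2, 2 without sibling 3 and 4 without sibling 4. In those fits the epidermal median was 0.05, -0.01, 0.08 and -0.02, against 0.29 with all libraries. Without the block, leaving out a single library leaves its replicate number in only 1 group. These changes can thus not be told apart from differences between replicate numbers.

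**Figure D4:**
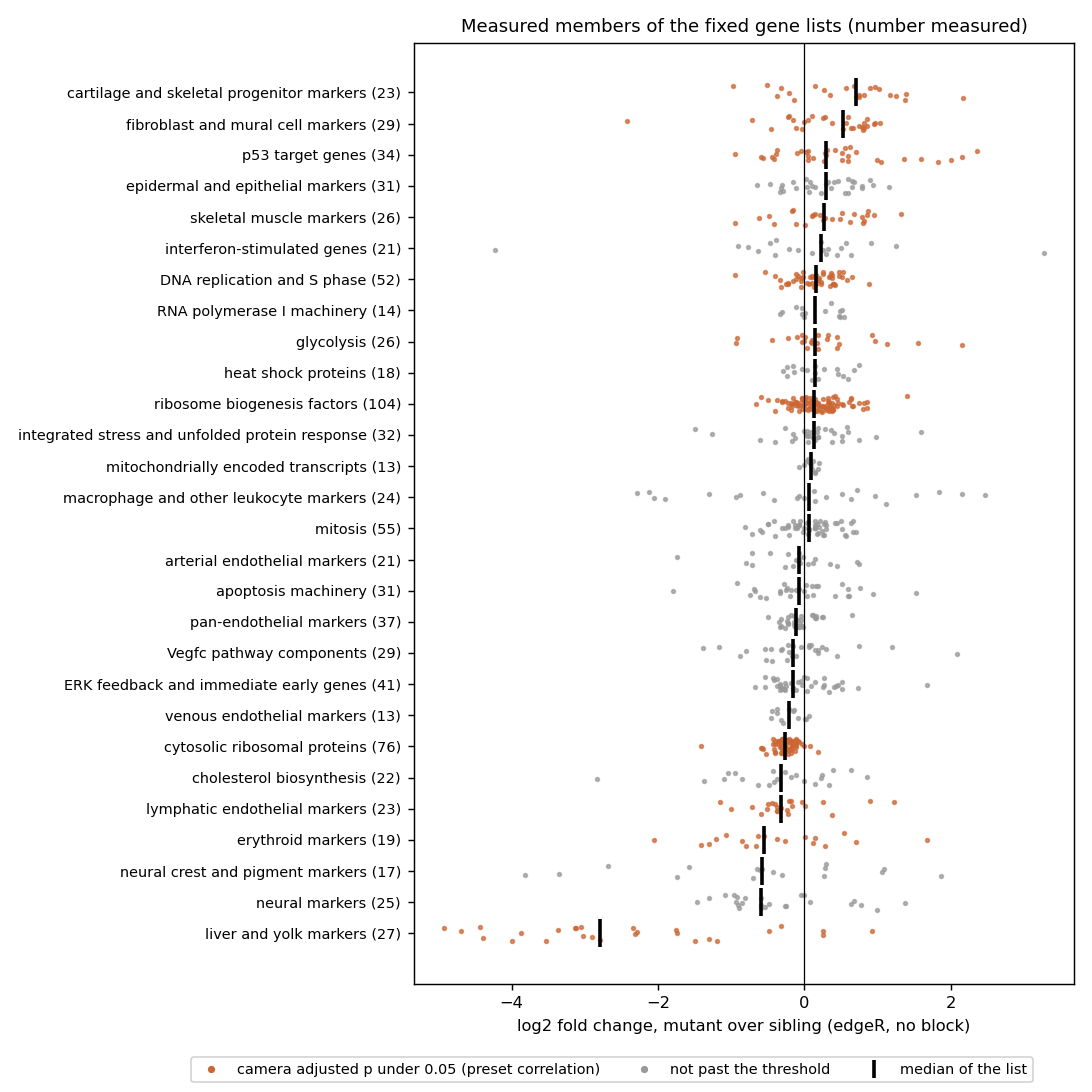
Log2 fold changes (mutant over sibling, edgeR without the block) of the measured members of each of the 28 gene lists, 1 point per gene, with the list median as a black bar and the number measured in brackets. Orange lists passed camera with its preset correlation; the liver and yolk list stands apart with a median of -2.80, while 74 of the 76 ribosomal protein members lie below 0, with a median of -0.27.

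Outside the lists, the rule for named genes took few others. PARP3, a DNA repair enzyme, measured 31 ± 7.99 against 75.7 ± 9.23 CPM in mutants (SD, n = 4 each; log2 1.29, SE 0.25). SMARCAD1 (ENSDARG00000014041), a chromatin remodeller, measured 9.4 ± 2.78 against 36.3 ± 13.3 CPM (log2 1.95, SE 0.38). The myelin gene plp1b measured 18.5 ± 7.03 against 3.81 ± 0.754 CPM (log2 -2.28, SE 0.44). Every mutant library lay on the same side of every sibling library for these 3, but none passed over all genes in edgeR (adjusted p = 0.71 for each). DESeq2 called all 3 (adjusted p = 0.0034 for PARP3, 0.0022 for SMARCAD1 and 0.00013 for plp1b). With the block, gpx4a, a glutathione peroxidase, had a log2 fold change of -1.37 (SE 0.17) and col18a1a, a basement membrane collagen, of 1.34 (SE 0.16). Both went in the same direction in 4 of 4 pairs and neither passed in edgeR (adjusted p = 0.45 for each). With the block limma-voom (adjusted p = 0.027 for each) and DESeq2 (adjusted p = 6.3e-09 and 4.7e-11) called both.

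The second deposited table, labelled as batch-corrected log2 CPM, held for all 260160 values the log2 of CPM + 1 of the raw counts (within 1e-09), so no correction was present in it. Mutant minus sibling differences of its means correlated with the edgeR log2 fold changes at r = 0.844 and rho = 0.928 over 18549 genes. Over the 11354 with a mean of at least 5 CPM they did so at r = 0.921 and rho = 0.942. These are correlations across genes, which are not independent replicates.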

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

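Of the tests below, those on epidermal RNA and on a lower share of the sorted cells for p53, all those on liver transcripts other than the splits and the one on shared variation for ribosomal proteins were chosen only after the result was seen, whereas the counts of splits and the test of epidermal RNA for ribosomal proteins were not. The test of p53 targets against epidermal RNA was rewritten after part of its outcome was known.

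In 15 of 308 groups of 4 libraries tested, 1 library lay apart from the other 3 by more than 0.829 of the group's range, where chance gives about 1 in 20 groups. Mutant 1 was the one apart in 5 groups. It was lowest for TBX1 (gap 0.982 of the range, log2 CPM 5.97 against 6.47 in the nearest library), the erythroid markers (0.959, mean 3.3 against 4.24), mt-nd4l (0.85, 4.65 against 5.74) and apoa1b (0.836, 3.62 against 4.74), and highest for NAT10 (0.874, 6.5 against 5.42). Sibling 2 was highest for the heat shock list (0.892), the ERK feedback list (0.885) and YAP1 (0.833). Mutant 3 was highest for cxcl11.1 (0.934) and lowest for HRAS (ENSDARG00000005651; 0.844). Mutant 4 was lowest for HSPE1 (0.87) and cycsb (0.837). Single groups had sibling 4 lowest for the RNA polymerase I list (0.978), sibling 3 lowest for hsp90aa1.1 (0.866) and sibling 1 highest for ELAVL4 (0.859).

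The 8 libraries can be split into 4 and 4 in 35 ways, of which 8 part all 4 same-numbered pairs as the genotypes do. The genotypes gave 0 genes past the threshold in edgeR, so all 35 splits gave as many or more by construction and this count tests nothing. The highest of the others gave 517. That split sets replicates 1 and 2 against 3 and 4 and points to a structure of the samples. In it 21 epidermal and 22 pan-endothelial markers passed, with medians of 2.37 and -0.96. At an unadjusted p under 0.05, 12 splits gave at least the 556 genes of the genotypes, up to 2390, but the other 7 that part all pairs gave at most 297. In DESeq2 5 splits gave at least 62 genes, up to 1178, against at most 27 among those that part all pairs. For the other 26 lists, 9 splits called at least 9, up to 14, against at most 4 among those. Chance can thus not be excluded over all splits for the counts at an unadjusted p, in DESeq2 and of lists. The splits that keep pairs together also carry the differences between replicate numbers.

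The p53 targets were higher in mutants. Only 1 split of 35, the genotypes, gave a camera p as small as 5e-08 (smallest of the others 7e-05). It alone called as many as 6 members (highest other 3). The 35 are not alike, since the libraries pair by replicate number. The 8 that part all pairs (other smallest p 0.002, highest other 0 members) are too few for a share under 0.05, so the splits cannot exclude chance. More epidermal RNA in the mutants is argued against as the cause only as far as the epidermal score tracks it, since with that score as a covariate all 6 members were still called. The median of the epidermal markers went from 0.29 to 0.01 by construction, since the score is their own mean log2 CPM. The score differed mainly between replicate numbers, from 4.48 in sibling 4 to 8.12 in mutant 2. An even rise of all other cell types, as a lower share of the sorted cells could give, is argued against too. For 3 such lists fell or held members that fell, although only the liver and yolk list did so without each library in turn (10 to 15 members). The muscle, cartilage and fibroblast lists were called as higher, but not with an estimated correlation (adjusted p = 0.55 to 0.65). Other cell types need not rise alike, so a lower share of the sorted cells itself stays open. Of the pan-endothelial markers 29 of 37 lay below 0, with a median of -0.11 (camera adjusted p = 0.50). That loss of Ddx21 raised p53 activity in these cells is a hypothesis that may account for the pattern, found and tested on the same data. More RNA of muscle, cartilage or fibroblast cells, whose lists were called as higher, stays open, as does epidermal RNA that the score does not track. A change within another cell type and differences in handling between mutant and sibling sorts stay open too, and the labels give no value to test them.

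The liver and yolk transcripts were lower in mutants. Only 1 split of 35, the genotypes, called as many as 15 members (highest other 2). The 35 are not alike, since the libraries pair by replicate number. The 8 that part all pairs (highest other 0) are too few for a share under 0.05, so the splits cannot exclude chance. Less RNA of every other cell type is argued against, since 4 of the 8 other lists of such cells were called as higher with the block (not with an estimated correlation, adjusted p = 0.12 to 0.47) and 8 epidermal, 7 muscle and 5 fibroblast members rose there, adjusted over the list alone, and 1 mutant library alone is argued against, since at least 12 members fell without any 1 of them. Less RNA of digestive organs cannot be told apart from a change specific to liver transcripts: exocrine pancreas genes had a median of -2.66 with the block, but that list was drawn up after its genes were seen, its median without the block was -4.55 and only -0.89 without sibling 4, and neither it nor the intestinal list was called with an estimated correlation (adjusted p = 0.12 and 0.35 with the block). The gate should exclude the cells that make liver proteins, yet tfa stood at 538 ± 398 CPM in siblings, so free RNA or carried-through cells may be the source. The level of apoeb (8690 ± 8580 CPM in siblings), which did not fall, is not evidence on this point. A smaller or later liver in the mutant embryos stays open as an untested biological explanation.

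The ribosomal protein transcripts were lower in mutants as a list, but 10 splits of 35 gave a camera p as small as 5.4e-09 (smallest of the others 1.5e-26), as did 2 of the 8 that part all pairs (other smallest 1.9e-12), so chance cannot be excluded. For ribosome biogenesis factors 13 splits gave a p as small as 0.00027 (smallest of the others 4.3e-14), and 4 of those 8 did (other smallest 3.3e-09). More epidermal RNA in the mutants, as far as the epidermal score tracks it, is argued against for the ribosomal proteins. Their median went from -0.27 to -0.35 with that score as a covariate (SD 0.19 over members). Variation between libraries that these genes share is a candidate explanation. The camera adjusted p of 0.65 with the correlation estimated is the value it needs, but does not favour it over others. Only 2 of the 28 lists were called in that setting. An effect of the genotype stays open as an untested biological explanation, and mutants 1 and 4, in which the list was lowest, also had low quality weights.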

How the results depend on the processing

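The alternatives chosen only after the data had been seen were the replicate block in DESeq2 and in limma-voom, leaving out the 3 libraries of lowest quality weight, the epidermal score as a covariate and the block with an estimated correlation. Where a value changed, the cause was not tested. By construction, though, a test on fewer libraries asks for larger differences, as does one that lets genes of a list vary together. Leaving out a single library from a fit without the block also unbalances the replicate numbers between the groups.

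The main statements held widely. DDX21 stayed lower without passing under every alternative, with a log2 fold change of -0.64 to -0.35 without single libraries or pairs. The p53 target genes as a list kept its direction under every alternative, with camera adjusted p = 3.4e-09 to 0.00034 without single libraries or pairs. With the block its call ended with an estimated correlation (adjusted p = 0.12) and in fry (0.066). Without single libraries or pairs 5 to 8 single p53 targets rose, and 62 to 76 of the ribosomal proteins had values below 0. Scaling by the median ratio, the upper quartile or library size alone left 5 of the 6 single p53 calls and all the list calls named here, and it moved the median log2 fold change of all genes to between -0.03 and 0.01. Without a filter on low counts that median was -0.11.

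The count of genes depended on the tool. edgeR called 0 genes with each other scaling, with a threshold of 0.01 or 0.1, with the block and without each library or pair. It called 1 gene, a higher one, with no filter on low counts. DESeq2 called 62 (13 higher, 49 lower), and limma on the deposited log2 CPM called 2. With 1 surrogate variable edgeR called 0, with 729 at an unadjusted p under 0.05, and limma-voom with quality weights called 0, with 860. With the block edgeR gave 1086 at an unadjusted p under 0.05 and called 11 of the other 26 lists against 9, DESeq2 called 526 genes (183 higher, 343 lower) and, adjusted over the list alone, 23 lower liver and yolk members, and limma-voom called 31 genes (14 higher, 17 lower). The calls of camera and of single genes that the block changed in edgeR stand beside their results in the report, and it changed no other of these. In fry the block ended the call of the p53 targets (adjusted p = 0.034 without it and 0.066 with it) and brought in the epidermal, fibroblast and glycolysis lists (0.021 each, against 0.83, 0.57 and 0.57).

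Ribosome biogenesis factors were not called with an estimated correlation (adjusted p = 0.66), with fry (0.72) or with the block and an estimated correlation (0.57), and ranged from 3e-07 to 0.61 without single libraries or pairs. The call ended without pair 1 (0.61) and pair 3 (0.054). Of the other 26 lists, 1 was called with an estimated correlation and 1 with fry, 3 on the deposited log2 CPM, 4 without the 3 libraries of lowest weight, 5 with the epidermal score and 0 with the block and an estimated correlation. Without single libraries or pairs the count was 2 to 13. Lower liver and yolk members numbered 9 to 16, with 9 without pair 2 in the block fit.

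Without the 3 libraries of lowest weight 3 p53 targets rose. There 32 ribosomal proteins had values below 0 and their list pointed higher (camera adjusted p = 0.87). The correlation with the deposited log2 values was 0.921 over genes of at least 5 CPM, against 0.844 over all.

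Some lists that did not pass changed direction, none of them passing in the new one. With no filter these were apoptosis machinery (adjusted p = 0.84), arterial markers (0.89) and interferon-stimulated genes (0.89), the last also with the stricter filter (adjusted p of 1). With limma-voom they were apoptosis (0.9), arterial (0.39) and pan-endothelial markers (0.28), with 1 surrogate variable arterial markers (0.86), and with limma-voom and the block leukocyte markers (0.8). Without the 3 libraries of lowest weight they were apoptosis (0.91), arterial (0.17), pan-endothelial (0.2) and leukocyte markers (0.08), and with the epidermal score arterial and pan-endothelial markers (0.33 each). Without single libraries or pairs the adjusted p ranged from 0.19 to 0.8 for arterial, 0.0037 to 0.88 for pan-endothelial and 0.07 to 0.87 for leukocyte markers. It ranged from 0.33 to 0.94 for the Vegfc pathway, 0.55 to 0.9 for interferon-stimulated genes, 0.6 to 0.99 for apoptosis, 0.0016 to 0.88 for mitosis, 0.0022 to 0.94 for ERK feedback genes and 0.032 to 0.84 for heat shock proteins. The values under 0.05 kept the direction of the full set. Pan-endothelial markers were called as lower without sibling 1 (0.044), sibling 2 (0.014), mutant 4 (0.0037), pair 2 (0.0083) or pair 4 (0.05 after rounding). So were venous endothelial markers as a list without sibling 2 (0.0088) or mutant 4 (0.0052), and neural markers as a list without sibling 2 (0.013). Mitosis genes were called as higher without mutant 1 (0.016) or pair 1 (0.0016), ERK feedback genes as lower without pair 1 (0.0022), and heat shock proteins as higher without mutant 3 (0.032).

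Among named genes, kdrl, which did not pass, had a log2 fold change of 0.14 with limma-voom, 0.01 with limma-voom and the block, 0 with 1 surrogate variable, 0 without the 3 libraries of lowest weight and 0.11 with the epidermal score, and PROX1 had 0.19 without those 3. Without single libraries or pairs the range was -0.34 to 0.14 for kdrl, -0.5 to 0 for FLI1, -0.03 to 0.3 for MT-ATP6, 0 to 0.37 for MT-CYB, 0 to 0.4 for mt-nd4l, -0.07 to 1.12 for PPL and -1.19 to 0 for myhz2. Over all alternatives, 585 list values kept their direction and their side of the threshold, 95 lost their call, 34 gained one and 42 changed direction. For named genes 3311 kept both, 79 gained a call over all genes and 17 changed sign. Among genes that did not pass in edgeR without the block, DESeq2 with the block called over all genes cdkn1a (adjusted p = 0.014), OSR2 (0.033), WDR3 (0.0054), utp3 (0.028), RPS9 (0.0054), RPL10A (0.0016), HSPA5 (0.019), GAPDH (0.0017) and DUSP1 (0.0059). The spread between libraries limits the calls, and whether part of it reflects how many RNA molecules were sampled was not tested.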

Other observations

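The lists of exocrine pancreas, intestinal and lens genes, and their tests, were chosen only after the values had been seen. Exocrine pancreas genes were lower in mutants, with 14 of 14 log2 fold changes below 0, a median of -4.55 and all 14 falling, adjusted over the list alone (camera adjusted p = 2e-10 over 3 lists; adjusted p = 0.31 with an estimated correlation). With the block the median was -2.66 and 10 fell (adjusted p = 0.12 with an estimated correlation). The size rested on sibling 4, whose mean log2 CPM over the list was 10.89 against 4.57 to 5.49 in the other siblings and 1.71 to 4.82 in mutants, and without it the median was -0.89. The elastase gene ela2 measured 2290 ± 4410 CPM in siblings and 40.5 ± 41.5 in mutants (SD, n = 4 each). Intestinal genes had a median of -1.28 (11 measured, camera adjusted p = 0.016; adjusted p = 0.32 with an estimated correlation), and -0.26 without sibling 3. Lens crystallin genes had a median of 0.51 (13 measured, adjusted p = 0.048; adjusted p = 0.54 with an estimated correlation), -0.30 without mutant 1, and 0.12 with the block (adjusted p = 0.12).

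DESeq2, DESeq2 with the block and limma-voom with the block called 62, 526 and 31 genes over all genes, and 10 genes were shared by all 3. The shared genes hold p53 targets, among them CCNG1 and rps27l, and 2 liver and yolk genes, apoa1b and ces2a. Outside both lists were EOMES (ENSDARG00000006640), UCP1, synpo2b, mat2al and the unnamed gene ENSDARG00000090943. Near the floor were EOMES, synpo2b and ENSDARG00000090943, at means of 2.55, 1.74 and 1.99 CPM (DESeq2 log2 fold change -10.4, 9.71 and -10.04). UCP1 had a mean of 29.4 CPM (log2 -2.46) and mat2al of 108 CPM (log2 2.18). All 3 fits used the same counts and 2 were DESeq2, so sharing a call is not independent support.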
